A study of Mus musculus with 2 samples.

How the data were processed

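The data are 2 polyadenylated RNA libraries of mouse G1E-ER4 cells treated with 10 nM estradiol for 24 h, sequenced from both ends of the fragments. Per the labels, the values were made on the mm10 assembly, and per the text deposited beside the tables the annotation was GENCODE M4 and the quantification started from alignments to the transcriptome. The aligner, the quantification tool and its version, read filters, and whether strand was used are not given in the sources used here. The deposited gene and transcript tables hold estimated counts that need not be whole, as maximum likelihood and posterior mean values. The deposited TPM (transcripts-per-million) values are corrected for effective length, and so are the deposited FPKM values, which are scaled by kilobase and by the number of fragments. The deposited transcript tables also give each transcript's percent of its gene's TPM. The series title says that a later series supersedes it; that series was not used here.

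Each gene table has 69691 entries, 43346 mouse genes, 26248 transfer RNA entries and 97 spike-in entries. The entries that are not genes held 3 counts in replicate 1 and 0 in replicate 2 and were left out of the library sizes. Symbols and positions were taken from GENCODE M21 by identifier without its version, on the same assembly. This named 42462 genes, with 20 symbols shared by more than 1 entry, and left 884 without a symbol, which entered the tests across all genes but no gene list. The gap between length and effective length was 152 bases in replicate 1 and 130 in replicate 2. Total counts were 70451042 and 13841487. Shares of counts carry Wilson intervals at 95%, and a count of 0 is given the limit of 3 counts of the library total.

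The labels put both libraries in 1 group, so no comparison between groups and no paired analysis was made. The results, tests, lists and rule for named genes of the report were chosen before the data were examined; later choices are named where they appear. Levels are the mean and SD of the 2 TPM values, and a gene was called detected with at least 1 TPM in both libraries. For 18 gene lists and 8 lists of markers of other cell types, the median of the members that passed was ranked among 10000 random lists of the same size drawn from detected genes. For 16 ratios, the log2 of summed TPM with a pseudocount of 0.1 was compared with the 95th percentile of the size of the log2 difference between the libraries among the 500 genes nearest in mean expression to the lower member. Symbols of the lists with no matching entry were Hbb-b1, Hbb-b2, Ahsp, Eraf and Rn7sl1, which were not analysed here.

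To set the libraries side by side, estimated counts were rounded to whole numbers and scaled by TMM in edgeR 4.0.16 (factors 1.15 and 0.871). Genes with a mean CPM of at least 1 were tested with a two-sided exact binomial test against the share expected from the scaled library sizes, with Benjamini-Hochberg adjustment, and counted with an adjusted p under 0.05 and at least 2-fold. A prior count of 0.5 was used for log2 ratios. A fold against 0 counts is a lower bound from 3 counts, and a ratio with 1 to 3 counts carries an exact 95% interval. The common dispersion came from edgeR with an intercept alone. For each list the median log2 ratio was ranked among 10000 random lists matched in 20 bins of expression. The leading transcript was the one with the highest percent, in genes with at least 10 TPM and more than 1 transcript. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used.

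The steps were tested on simulated data drawn from the mean levels and depths of the 2 libraries. Of 8863 simulated genes tested for replicate differences, all 100 with a true fold of 3 and all 100 with a true fold of 8 were called, and 0 of 8663 unchanged genes. For replicate differences by list, a planted list reached the 100th percentile and 8 of 200 random lists (4%) fell outside the central 95%. In both of these tests counts were drawn for each gene independently with counting error only, so genes that vary together were not simulated. For the dispersion over 8710 simulated genes, a coefficient of 0.632 was estimated as 0.630.

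The named genes are the 10 with the highest mean TPM outside the mitochondrial genome, the 3 highest and the lowest of each gene list, the 2 highest of each other cell type, the genes of the ratios, the 10 with the largest fold in each direction between the replicates (mean CPM of at least 10), the fixed isoform genes with at least 10 TPM, and Gata1 and Esr1. Some genes that the rule takes in, and the ratios that need them, are not reported here. Genes named outside this rule are said to be so where they appear. Alternatives were other minimum levels (0.5 or 5 TPM, 1 FPKM, 10 counts, no minimum), posterior means, TPM without mitochondrial and globin genes, TMM-scaled CPM, a pseudocount of 1, DESeq2 1.42.0 size factors, total counts, a mean CPM of 10, a fold of 1.5, gene levels of 1 or 50 TPM for isoforms, and each library alone. For each library alone, the members of a list were those with at least 1 TPM in that library, so their number can differ. Total counts for the lists was added after seeing the data.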

Results

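Polyadenylated RNA was measured by paired-end sequencing in G1E-ER4 cells, a mouse erythroid line that lacks its own functional Gata1 and carries GATA1 fused to the ligand-binding part of an estrogen receptor, so that estradiol releases GATA1 activity and starts terminal erythroid differentiation. The labels give 1 group, cells treated with 10 nM estradiol for 24 h, with 2 libraries named biological replicates 1 and 2. Both carry the same biosample record, so the spread between them may be technical, and no untreated sample was analysed here. The gene tables summed to 70451042 estimated counts in replicate 1 and 13841487 in replicate 2, a 5.09-fold difference in depth. A count of 0 therefore allowed up to 0.0426 in counts-per-million (CPM) in replicate 1 and 0.217 CPM in replicate 2, taking 3 counts as the limit. Levels below are mean transcripts-per-million (TPM) ± SD with n = 2, and intervals and limits cover counting error only, since the labels name no molecular identifiers. With 1 group no comparison between conditions could be made, and a two-sided exact sign-flip test on 2 libraries cannot go below p = 0.5. The questions addressed were which genes these cells expressed after 24 h of estradiol, how the levels of alternative genes compared within a library, and how far the replicates lay apart.

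Hemoglobin and iron storage transcripts led the profile. The adult beta globin gene Hbb-bs (ENSMUSG00000052305.5, mm10 chromosome 7, 103826534 to 103828096, minus strand) had the highest level, 84105 ± 54833 TPM. The alpha globin genes Hba-a1 and Hba-a2 followed with 52936 ± 24774 and 17978 ± 22327 TPM; they are near-identical copies, so their split is uncertain, and their sum was 70914 ± 47101 TPM. Ferritin light chain Ftl1 reached 40272 ± 5389 TPM and ferritin heavy chain Fth1 23663 ± 8992 TPM. The other genes among the 10 highest were prothymosin alpha, Ptma (17429 ± 12975 TPM), the ribosomal stalk protein gene Rplp1 (16496 ± 90.2 TPM), the histone gene Hist1h2ad (12851 ± 14518 TPM), and Gm42418 (14336 ± 7133 TPM) and Gm26917 (13002 ± 11498 TPM). Gm42418 (chromosome 17, 39846958 to 39848788) overlaps an annotated ribosomal RNA pseudogene, and Gm26917 lies beside it, so their counts are not read as messenger RNA. Each library's own 10 highest genes took 35.9% of its TPM in replicate 1 and 27.0% in replicate 2.

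The adult alpha and beta globin genes together took 8.61% of counts in replicate 1 (95% Wilson interval 8.61 to 8.62%) and 3.25% in replicate 2 (3.24 to 3.26%), or 15.6 ± 10.3% of TPM. Ribosomal protein genes took 7.99 ± 3.56% of TPM, the ferritin genes 6.39 ± 1.44%, histone genes 4.08 ± 0.21% and mitochondrially encoded genes 0.291 ± 0.0557%. Of counts, mitochondrially encoded genes took 0.262% in replicate 1 and 0.0939% in replicate 2. At least 1 TPM was reached in both libraries by 7444 genes, of which 7107 were protein coding. Another 1105 genes reached it in replicate 1 and not in replicate 2, and 463 in replicate 2 and not in replicate 1. The 5678 genes with a mean CPM of at least 10 were compared by log2 of TPM with 1 added. The libraries gave a Pearson r of 0.78 and a Spearman rho of 0.75, across genes, which are not independent replicates. The SD of the difference between these log2 values was 1.38.

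**Figure D1:**
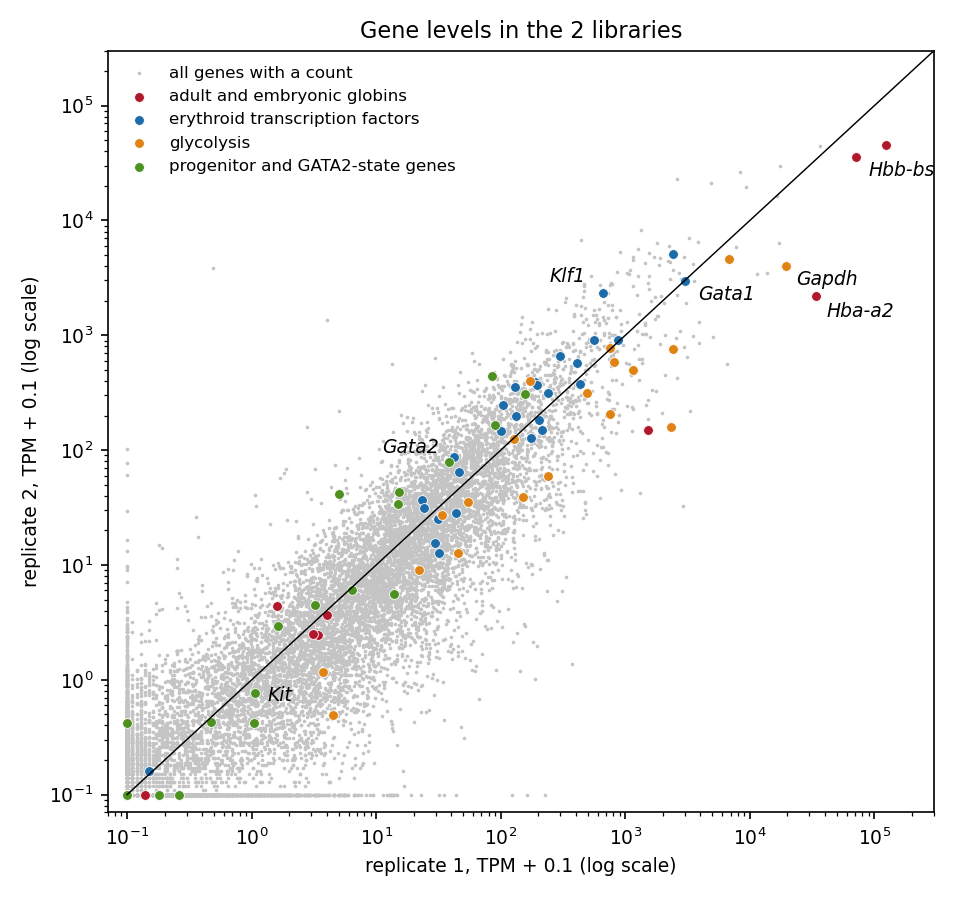
TPM of each gene in replicate 1 (x axis) and replicate 2 (y axis), both axes logarithmic with 0.1 added, each point a gene, coloured for members of 4 lists, and the line marking equal levels. Named points include Gata1, with 3038 and 2940 TPM, and Hbb-bs, with 122878 and 45332 TPM.

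Gata1 itself (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071, minus strand), the gene of the fusion's transcription factor part, had 3038 TPM in replicate 1 and 2940 TPM in replicate 2, or 2989 ± 69.4 TPM. Reads from the gene and from the fusion transcript fall in the same gene entry. Esr1 (ENSMUSG00000019768.12, chromosome 10, 4611593 to 5005614), the mouse estrogen receptor alpha gene, had 0 and 1 counts; the species of the receptor part is not given in the sources used here. Of 28 measured erythroid transcription factor genes, 26 had at least 1 TPM in both libraries, with a median of 188 TPM, which lay at the 100th percentile of 10000 random lists of the same size drawn from expressed genes. Zfpm1, which encodes the GATA1 cofactor FOG1, was the highest with 3740 ± 1901 TPM. Klf1, an activator of the adult beta globin gene, had 1508 ± 1192 TPM, and Tal1, a partner of GATA1 at erythroid enhancers, had 488 ± 114 TPM. Sox6 was the lowest with 16 and 0 counts.

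All 20 heme synthesis and transport genes passed 1 TPM in both libraries, with a median of 169 TPM (100th percentile). Blvrb, a biliverdin reductase, had 3265 ± 451 TPM, the heme pathway enzyme Alad 848 ± 622 TPM, and Tmem14c, which carries a heme precursor into mitochondria, 815 ± 364 TPM, while the housekeeping enzyme Alas1 had 2.60 ± 0.453 TPM. Of 26 membrane and cytoskeleton genes 23 passed, with a median of 113 TPM (100th percentile; 102 TPM in replicate 1 alone and 68.6 in replicate 2 alone), led by carbonic anhydrase Car2 (796.9 ± 88.1 TPM), beta spectrin Sptb (793 ± 304 TPM) and the adducin gene Add1 (760.4 ± 74.1 TPM). The water channel gene Aqp1 had 0 counts in both libraries. Of 11 globin genes 8 passed with a median of 416 TPM (100th percentile), a value that lies between a high adult and a low embryonic part of the list; Hbb-bh2 had 0 counts. Their median was 756 TPM in replicate 1 alone and 76.5 TPM in replicate 2 alone. With posterior mean TPM 9 members passed, the median was 6.65 TPM and the percentile 12.985. All 15 iron handling genes passed, yet their median of 20.4 TPM lay at the 55.9th percentile: beside the ferritin genes and the iron chaperone Pcbp1 (2824 ± 2356 TPM), the iron-sensing protein gene Ireb2 had 1.80 ± 0.262 TPM. The median of this list was 25.2 TPM in replicate 1 alone and 9.25 TPM in replicate 2 alone.

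Of 24 measured progenitor genes of the GATA2 state 11 had at least 1 TPM in both libraries, 6 were at 0 in both, and the median of those that passed was 24.3 TPM (67.9th percentile). In replicate 1 alone that median was 14.8 TPM (51.4th percentile) and in replicate 2 alone 41.7 TPM (94.8th percentile). Hhex (266 ± 255 TPM), Runx1 (231 ± 107 TPM) and Myc (126.9 ± 53.6 TPM) were the highest, and Hoxb4 had 0 counts. Among 24 cytokine receptor and JAK-STAT genes 19 passed, with a median of 30.1 TPM (85.8th percentile). Csf2rb, the shared beta chain of the receptors for interleukin 3 and GM-CSF, had 2982 ± 2586 TPM, its relative Csf2rb2 359.7 ± 48.9 TPM and the kinase gene Pim1 1112 ± 948 TPM.

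**Figure D2:**
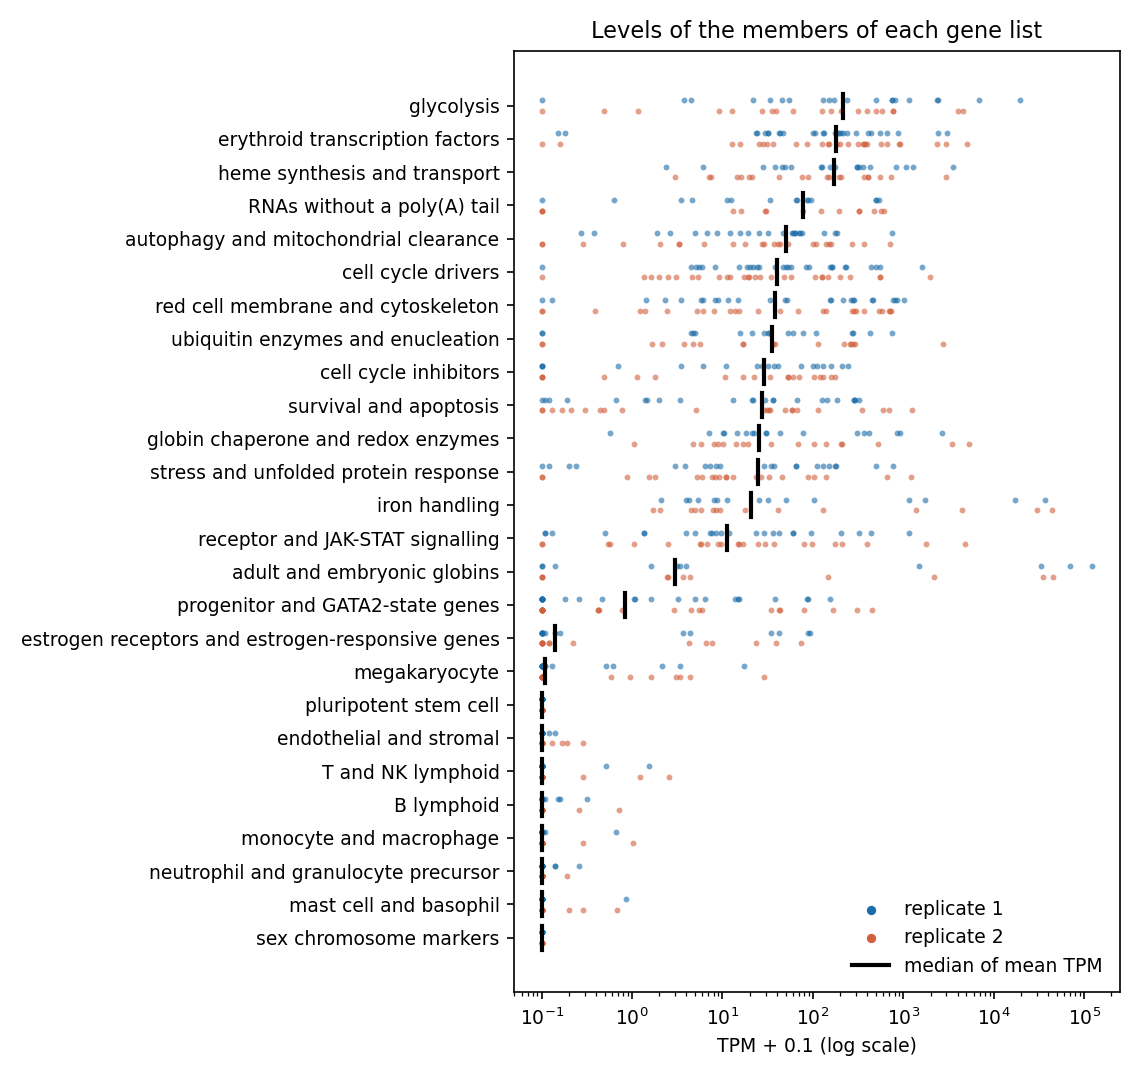
TPM in each library (x axis, logarithmic, 0.1 added) of every measured member of each fixed list, blue for replicate 1 and red for replicate 2, with a black bar at the median of the members' mean TPM. Over all measured members the medians ran from 0 TPM for pluripotent stem cell genes to 217 TPM for glycolysis and 178 TPM for erythroid transcription factors.

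Ratios were taken between fixed pairs of genes within each library. Gata1, whose entry also takes reads of the introduced fusion, exceeded Gata2 by 5.76 ± 0.78 on the log2 scale (Gata2 58.7 ± 29.2 TPM) and exceeded Spi1, the myeloid factor PU.1, by 8.92 ± 0.02 (Spi1 6.07 ± 0.24 TPM). Adult Hbb-bs and Hbb-bt exceeded the embryonic genes Hbb-y and Hbb-bh1 by 13.72 ± 0.74, and the adult alpha genes exceeded embryonic Hba-x by 14.00 ± 0.94. Alas2, the erythroid aminolevulinate synthase, exceeded Alas1 by 5.86 ± 1.71. The noncoding transcript Alas2-204 held 236.57 of the 320.57 TPM of Alas2 in replicate 1, against 1 of 75.97 TPM in replicate 2. The mitochondrial iron importer Slc25a37 exceeded Slc25a28 by 3.69 ± 0.20. Its transcript Slc25a37-204, annotated as subject to nonsense-mediated decay, held 223.23 of 360.53 TPM in replicate 1 and 144.76 of 206.68 TPM in replicate 2. The ratio for its coding transcripts alone was not taken. Beta spectrin Sptb exceeded its non-erythroid relative Sptbn1 by 11.51 ± 0.08. Klf1 exceeded Fli1, a factor of the megakaryocyte lineage, by 7.16 ± 2.23, and Tal1 exceeded Lyl1 by 6.98 ± 0.01. The erythropoietin receptor gene Epor (87.4 ± 12.2 TPM) exceeded Kit, the stem cell factor receptor (0.820 ± 0.212 TPM), by 6.58 ± 0.13. The survival gene Bcl2l1 exceeded Bcl2 by 11.36 ± 1.12, Ccnd3 exceeded Ccnd2 by 6.30 ± 0.62, and the inhibitor Cdkn1b exceeded Cdk6 by 7.76 ± 1.16.

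In all, 14 of the 16 fixed ratios had the same sign in both libraries and a mean larger than the replicate spread. This spread was the 95th percentile of the log2 difference between the libraries among the 500 genes nearest in expression to the lower member. It describes single genes, not ratios. Alpha over beta adult globin, with -0.26 ± 0.01 against a spread of 2.67, was among the 2 that did not exceed it. Where a denominator held 3 counts or fewer in replicate 2, the ratio of TPM without a pseudocount was 19821 for Bcl2l1 over Bcl2 (95% interval 3557 to 782888, 1 count of Bcl2, listed at 0.03 TPM) and 6419 for Sptb over Sptbn1 (2196 to 31125, 3 counts of Sptbn1, listed at 0.09 TPM). The size of ratios over genes near 0 depended on the pseudocount: with 1 in place of 0.1 the log2 ratio was 8.61 for Bcl2l1 over Bcl2, 9.35 for Sptb over Sptbn1, 6.49 for Cdkn1b over Cdk6 and 5.60 for Epor over Kit. The spread moved as well: for Bcl2l1 over Bcl2 it was 1.43 with 0.1, 0.19 with 1 and 3.66 in TMM-scaled CPM.

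**Figure D3:**
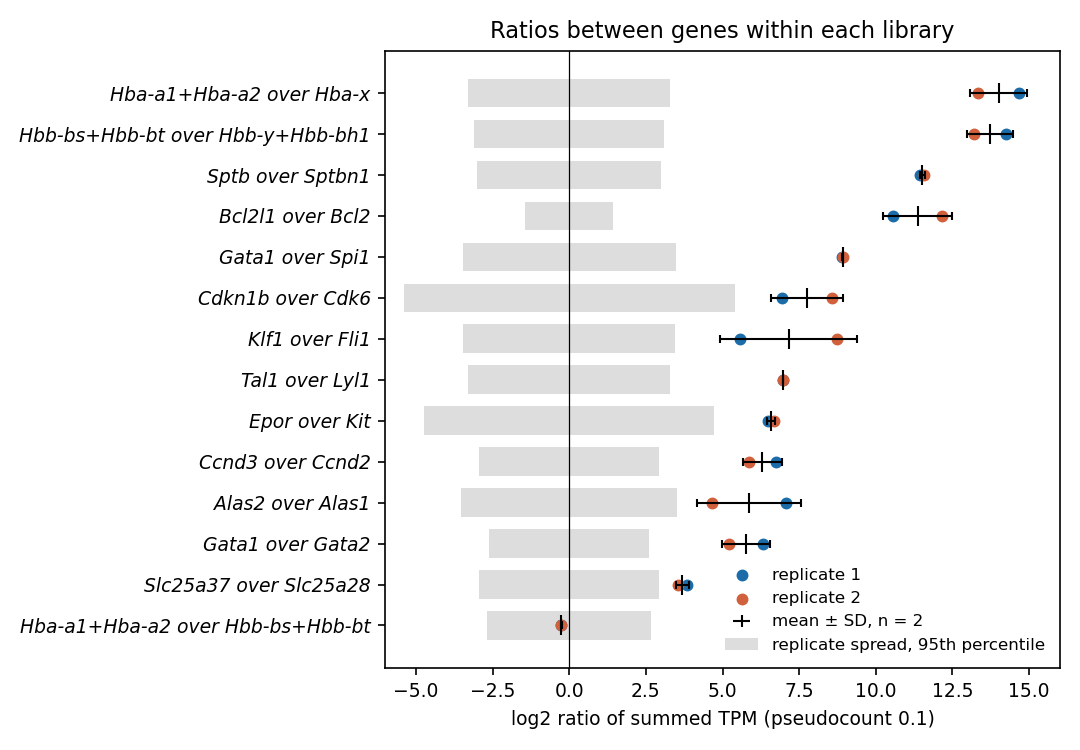
Log2 ratio of summed TPM (x axis, pseudocount 0.1) for the fixed pairs reported here, with points for each library, bars for mean ± SD (n = 2) and grey bands for the replicate spread of each pair. Of the pairs drawn, alpha over beta adult globin, at -0.26, lies inside its band and the others lie outside theirs.

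Genes for survival, clearance of organelles and energy supply were expressed beside the erythroid lists. Glycolysis genes had a median of 345 TPM (18 of 20 passed, 100th percentile). It was 240 TPM over 19 members in replicate 1 alone and 183 TPM over 18 in replicate 2 alone. Gapdh had 11736 ± 10912, Aldoa 5740 ± 1571 and Ldha 1600 ± 1181 TPM, and Ldhb had 0 counts. Survival and apoptosis genes had a median of 91.3 TPM (14 of 23, 99.9th percentile). It was 36.2 TPM over the 18 members that passed in replicate 1 alone and 58.6 TPM over 14 in replicate 2 alone. The BH3-only gene Bbc3 had 696 ± 779 TPM, the protective genes Mcl1 and Bcl2l1 498 ± 287 and 442 ± 217 TPM, and Bcl2a1b 0 counts. Autophagy and mitochondrial clearance genes had a median of 57.9 TPM (20 of 24, 99.2nd percentile), led by Gabarap (507 ± 331 TPM), the mitophagy receptor gene Bnip3l (382 ± 456 TPM) and Sqstm1 (277 ± 131 TPM). Ubiquitin and enucleation genes had a median of 46.6 TPM (16 of 18, 96.6th percentile), with Ube2c at 350 ± 106 and Rac2 at 265.3 ± 15.5 TPM, and Emp1 at 0 counts. That list lay at the 99.8th percentile in TMM-scaled CPM (median 118 CPM), the 99.4th with posterior mean TPM, the 99.5th with a minimum of 5 TPM (median 129 TPM) and the 98.0th without replicate 2. Stress and unfolded protein response genes had a median of 38.1 TPM (18 of 22, 92.9th percentile): Hspa8 had 863 ± 516, Ppp1r15a 711.3 ± 80.4 and Hsp90ab1 140 ± 50.9 TPM, and Atf3 0 counts. The stress list rested on the library used: its median was 51.0 TPM (99.6th percentile) in replicate 1 alone and 13.0 TPM (49.6th percentile) in replicate 2 alone. Redox genes had a median of 27.4 TPM (17 of 18, 78.8th percentile), with Gclm at 3093 ± 3086, Gpx4 at 3088 ± 533 and Gpx1 at 494 ± 500 TPM, and Nqo1 at 0.705 ± 0.332 TPM.

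Cell cycle genes were expressed on both sides. Of 28 drivers 27 passed, with a median of 40.9 TPM (97.7th percentile), led by the D-type cyclin gene Ccnd3 (1787 ± 273 TPM), Ccna2 (551.1 ± 7.58 TPM) and Cdk4 (379 ± 170 TPM), while Ccnd1 had 0 counts. Of 19 inhibitors 15 passed, with a median of 63.7 TPM (98.9th percentile), led by Gadd45a (158 ± 123 TPM), Cdkn1b (144.3 ± 22.7 TPM) and Cdkn2c (143.4 ± 21.3 TPM), while Cdkn2b had 0 counts. In total, 10 of the 18 gene lists lay within the top 2.5% of random lists. Of these, cell cycle drivers lay at the 89.0th percentile without replicate 1, with a median of 22.6 TPM, and at the 85.0th with a minimum of 5 TPM, autophagy genes at the 93.6th with that minimum, and survival genes and cell cycle inhibitors at the 96.9th and 97.0th without replicate 2, where the median of the inhibitors was 40.8 TPM. With posterior mean TPM the stress list (98.7th) and the JAK-STAT list (97.52nd) also passed, and with no minimum level the iron, progenitor, JAK-STAT, ubiquitin, redox and stress lists did.

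Of 15 estrogen receptor and estrogen-responsive genes 6 passed 1 TPM, with a median of 27.0 TPM (64th percentile; 38.5 TPM in replicate 1 alone and 15.4 in replicate 2 alone): the corepressor Ncor1 (81.5 ± 10.3 TPM), Ctsd (65.5 ± 37.2 TPM) and the coactivator Ncoa2 (32.8 ± 13.4 TPM) were the highest, and Cxcl12 had 0 counts. Of 16 megakaryocyte genes 3 passed, with a median of 3.30 TPM (4.315th percentile); Gp1ba had 23.0 ± 8.44 and Itga2b 3.30 ± 0.0354 TPM. Gata3, at 1.97 ± 0.721 TPM, was the 1 of 14 T and NK lymphoid genes that passed, and Klrb1c had 0 and 6 counts. No member passed in the lists for mast cells (Hdc 0.670 ± 0.113, Tpsb2 0.0950 ± 0.134 TPM), neutrophils (Prtn3 5 and 0 counts, Ngp 0 and 1), monocytes (Cd68 0.745 ± 0.247, Cd14 0.0950 ± 0.134 TPM), B cells (Cd79a 0.415 ± 0.276, Ebf1 0.0800 ± 0.113 TPM), or endothelial and stromal cells (Col1a1 0.105 ± 0.12, Kdr 0.0450 ± 0.0636 TPM). All 11 pluripotent stem cell genes, Pou5f1 and Nanog among them, were at 0 TPM in both libraries. Of 15 RNAs without a poly(A) tail, a list that also holds histone genes, 12 passed, with a median of 114 TPM (99.9th percentile; 67.3rd in TMM-scaled CPM, which does not correct for length): Rn7sk had 577.5 ± 52.6 TPM, the near-identical copies Rn7s1 and Rn7s2 had 410 ± 126 TPM each, and Snord118 had 0 counts. The median of that list was 66.7 TPM in replicate 1 alone and 159 TPM in replicate 2 alone. The labels name the donor as male; among 7 sex chromosome markers Xist had 6 and 0 counts, and Kdm5d, Ddx3y and Usp9y on the Y chromosome had 0 counts in both libraries.

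At the level of transcripts, the gene's leading isoform differed between the libraries in 988 of 3060 genes (32.3%) with at least 10 TPM and more than 1 annotated transcript. Of the 19 fixed genes at that level, 17 had more than 1 transcript and 14 of these had the same leading transcript in both libraries. Among these were Gata1, Bcl2l1, Epb41, Slc25a37, Tal1, Runx1, Pkm, Slc4a1, Bcl11a, Gfi1b, Zfpm1, Nfe2 and Foxo3, while Klf1 and Epor have a single annotated transcript. Gata1-201 made up 99.99% and 100% of its gene's TPM. The leading transcript of Slc25a37, Slc25a37-204, is annotated as subject to nonsense-mediated decay and took 61.9% and 70.0%. Epb41-215, a noncoding transcript, led in both libraries but took 85.7% of Epb41 in replicate 1 and 28.9% in replicate 2, where the coding Epb41-205 took 25.7% against 0% in replicate 1. Alas2, Ank1 and Lmo2 differed in their leading transcript. In Alas2 the short noncoding transcript Alas2-204 took 73.8% in replicate 1 and 1.31% in replicate 2, where the coding Alas2-201 led with 55.9%. Ank1-207 led with 41.5% in replicate 1 and Ank1-214 with 38.6% in replicate 2, and Lmo2-204 with 43.9% and Lmo2-206 with 82.1%. Short-read shares of overlapping isoforms are model estimates, and no error for them beyond the 2 libraries was used here.

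Between the replicates, many genes lay further apart than counting error allows. Of 8884 genes with a mean CPM of at least 1, 4256 differed at least 2-fold with an adjusted two-sided exact binomial p under 0.05, of which 1593 were higher in replicate 2 and 2663 in replicate 1 (37.4% higher in replicate 2). With total counts in place of TMM scaling the numbers were 942 and 3564 (20.9% higher in replicate 2), since the median log2 ratio of all genes moved from -0.20 to -0.61. The common biological coefficient of variation over these genes, from edgeR, was 0.684. This test compares these libraries against counting error and not any conditions.

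The 10 genes with the largest fold in each direction were as follows. Gm14036, a processed pseudogene, had 9 counts in replicate 1 and 15098 in replicate 2 (11252-fold after scaling), and the pseudogene Rpsa-ps2 97 and 5816 counts (402-fold). The loci Gm10801, Gm26870, Gm10800, Gm10719, Gm21738 and Gm10718 were 41.3-fold to 67.6-fold higher in replicate 2. They are not all separate places: Gm26870 (chromosome 9, 3000282 to 3038313) spans the positions of Gm10719 and Gm10718. Gm10801 and Gm10800 lie close together on chromosome 2 (from 98662237 and from 98666547). The histone gene Hist4h4 was 39.1-fold higher there, and Hist1h2aj, annotated as a pseudogene, 25.8-fold. In the other direction mt-Atp6, a mitochondrially encoded subunit of ATP synthase, had 8245 and 0 counts, by counting error alone at least 410-fold higher in replicate 1. The ribosomal protein gene Rps3a1 had 1999 and 0 counts, on the same terms at least 99.3-fold higher. These limits do not cover how reads were assigned to genes. Summed, the Rps3a genes were 24.0-fold apart, and mt-Atp8, whose reading frame overlaps mt-Atp6, had 666 TPM in replicate 1 and 1456 TPM in replicate 2. The proteasome gene Psmc5 had 4104 and 3 counts (204-fold, 95% interval 69.8 to 989), the ATP synthase gene Atp5h 3628 and 3 counts (180-fold, 61.7 to 874), and the complex I assembly gene Tmem126a 2243 and 4 counts (83.6-fold). Rps3a3, Gm10335, Gm11808, Rpl27-ps3 and Hypk were 51.4-fold to 117-fold higher in replicate 1. The largest adjusted exact binomial p among these 20 genes was 2.65e-120. Counts were whole numbers (within 0.005) in both libraries for Gm26870, Hist4h4, Psmc5 and Tmem126a, though Gm26870 spans Gm10719 and Gm10718, whose counts were fractional. The other 16 of these 20 genes had fractional counts in a library, as reads shared between genes give, and are uncertain.

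The 18 lists ranked were the gene lists other than sex markers, and the megakaryocyte markers. Of these, 5 lay outside the central 95% of random lists matched on expression. By chance 0.9 would if the genes of a list varied independently. Genes of a list that vary together can fall outside more often, so the number is a description. Glycolysis genes were lower in replicate 2, with a median log2 ratio of -1.13 over 19 members (0.03rd percentile, random median 0.45); 11 members were at least 2-fold higher in replicate 1 and 1 in replicate 2, with log2 ratios of -2.01 for Gapdh, -0.65 for Aldoa and -1.67 for Ldha. Heme synthesis genes had a median of -0.75 over 20 members (0.27th percentile); 6 were at least 2-fold higher in replicate 1 and 1 in replicate 2, with Blvrb at -0.37, Alad at -1.51 and Tmem14c at -0.78. Cell cycle drivers had -0.72 over 27 members (0.515th percentile), 10 higher in replicate 1 and 3 in replicate 2, with Cdk4 at -0.72 and Ccnd3 at 0.58. Progenitor genes were higher in replicate 2, with a median of 0.78 over 14 members (98.4th percentile), 6 at least 2-fold higher there and 2 lower, Hhex at 2.52 and Runx1 at 1.03, and so were RNAs without a poly(A) tail, with 0.89 over 12 members (99.4th percentile), 6 higher and 0 lower. With a minimum mean CPM of 10 the progenitor list (1.11) and the RNAs without a poly(A) tail (0.47) no longer lay outside, and the globin list did, at -2.20. At that minimum the globin list held only the 4 adult alpha and beta genes. Its median depends on how reads were split between near-identical copies: Hba-a1 and Hba-a2 summed had a log2 ratio of -0.74. The remaining 13 lists, erythroid transcription factors at 0.48, membrane genes at -0.21 and megakaryocyte genes at 1.01 among them, lay inside.

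**Figure D4:**
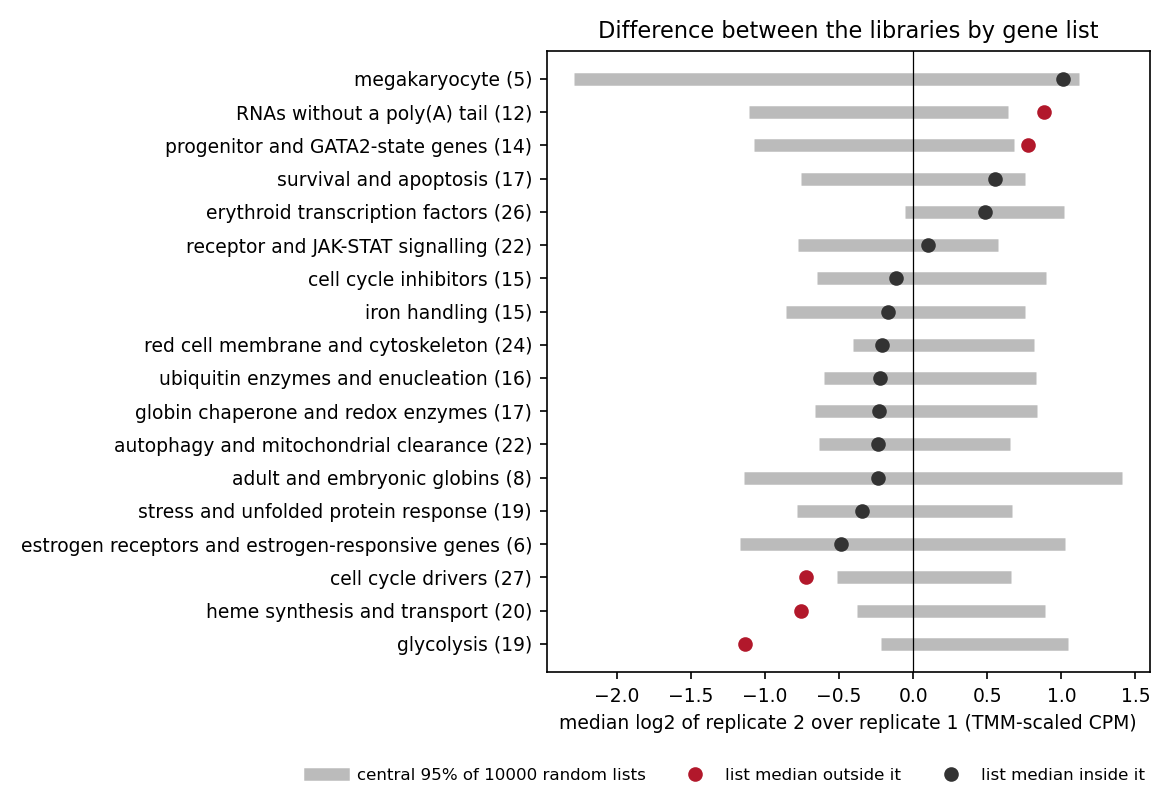
Median log2 ratio of replicate 2 over replicate 1 (x axis, TMM-scaled CPM) of each list, with the number of members tested, red where it lies outside the grey bar that spans the central 95% of 10000 random lists matched on expression. Glycolysis, heme synthesis and cell cycle drivers lie to the left of their bars and progenitor genes and RNAs without a poly(A) tail to the right.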

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

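Tests chosen only after the result was seen are that of GC content and length and that of molecule number over all genes, and the tests on Y-linked genes, where the GC test replaced earlier versions that had not decided; the other tests were fixed before their result. Genes without a symbol belong to no list or ratio of the report, yet they held counts above the limit of 3 counts that a count of 0 allows: 116796 in replicate 1 and 17840 in replicate 2. The highest of them by mean TPM were ENSMUSG00000096232.1, with 104 and 620 TPM, and ENSMUSG00000100725.2, with 373 and 304 TPM.

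Of 8884 genes, 4256 lay at least 2-fold apart between the libraries. Trends with GC content and gene length as the whole cause are argued against, since 3958 of 4235 calls were left after centring the log2 ratios in bins of both, among the genes with a GC content. Reads shared between similar genes are argued against as the whole cause too: 46.7% of 7895 genes with whole counts in both libraries were called, against 57.6% of the 989 others. Sampling of few distinct molecules would leave abundant genes close together, and is argued against as the whole cause for genes with a mean CPM of at least 10. The SD of the log2 ratio at a mean CPM of at least 1000 was 0.802 times that at 10 to 100 (95% bootstrap interval 0.679 to 0.925). It was 1.14 over 136 genes against 1.42 over 4043. Genes of lower expression were left out of this test, so it cannot decide for them. Their SD was 2.57 at a mean CPM of 1 to 3 and 1.84 at 3 to 10. Differences in culture, RNA preparation or library batch may contribute and stay open, since the labels give no batch, and no biological explanation was tested because there is 1 group.

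The glycolysis list was lower in replicate 2, with a median log2 ratio of -1.13 at the 0.03rd percentile of matched random lists. After the correction for GC content and length the median was -0.94 (random median 0.19) and its percentile 0.01. Over the 14 members with whole counts in both libraries the median was -1.07 (random median 0.50) and its percentile again 0.01. Neither GC content and length nor reads shared with the many pseudogenes of this pathway accounts for the whole shift. Other measures differed between the libraries too: RNAs without a poly(A) tail had a median of 0.89, ribosomal protein genes -1.60, Gm42418 and Gm26917 took 1.42% and 4.05% of TPM, and length minus effective length was 152 and 130 bases. A difference in the RNA or libraries, in the state of the cultures or in their handling may underlie it and was not tested, as the design names no group to compare.

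The 6 Y-linked genes examined had 0 counts in both libraries although the labels name the donor as male. Too little depth is argued against, since the smallest count of an X-linked homolog of these 6 genes was 33, for Zfx in replicate 2. A trend with GC content is argued against for Kdm5d (43.8%), since 4 of the homologs have a lower GC content and at least 33 counts. It cannot be told apart for the other 5 genes (35.7 to 39.2%), since no homolog lies under 40.6%. In the range of all 6 genes, 35.7 to 43.8%, 32.1% of 4376 protein-coding genes had over 3 counts in replicate 1, against 47.6% of all 21474. The share in the range of the 5 genes alone was not taken. Cells with an inactive X chromosome are argued against by Xist, whose highest level was 0.0852 CPM. Loss of the Y chromosome in culture, a donor other than the labels say, or another annotation of these genes may each apply and were not tested.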

How the results depend on the processing

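Outside the summary counts, 255 values kept their side of the limit, 16 passed it only under an alternative and 10 no longer passed. Values that had not passed could change direction among the 255: without replicate 1 the iron list went to the 29.1st percentile and the stress list to the 49.6th, and with no minimum level megakaryocyte genes went to the 90.2nd. Of values that had passed, 1 reversed: with posterior mean TPM the globin list lay at the 12.985th percentile, as 9 members passed and the median fell between them to 6.65 TPM. Of the summary counts, 28 stayed within 1.5 times the reported value. The number of gene lists within the top 2.5% of random lists was 16 with no minimum level, because the random lists then include genes at 0. Genes called between the replicates numbered 2496 with a mean CPM of at least 10, where 5678 genes were tested. Genes with a different leading transcript numbered 1910 with a minimum of 1 TPM and 364 with a minimum of 50 TPM, of 5519 and 1148 genes. With each library alone, detected genes ranged from 7907 to 8549, lists above the limit from 9 to 10 and ratios beyond the spread from 13 to 14. Isoform usage gives no value with a library left out, since it compares both. No paired analysis was possible because there is 1 group. The lists outside random lists numbered 5 with total counts, an alternative chosen after seeing the data. Depth leaves a gene with 0 counts in replicate 2 open up to 0.217 CPM. The SD of the log2 ratio was 2.57 at a mean CPM of 1 to 3, where 56.6% of genes were called; the cause was not tested.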

Other observations

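Gene families were also compared between the libraries; the families and the genes named here were chosen after their values were seen, and the directions of the family medians held under DESeq2 size factors and total counts. Ribosomal protein genes were lower in replicate 2, with a median log2 ratio of -1.60 over 82 genes (random median 0.11), 54 of them at least 2-fold lower and 4 at least 2-fold higher. Subunits of respiratory complex I had -1.87 over 35 genes, 23 lower and 2 higher, and proteasome subunits -1.54 over 33 genes, 21 lower and 0 higher. Nuclear-encoded ATP synthase subunits had -0.82 over 15 genes, at the 5.25th percentile and so inside the central 95% of random lists.

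Histone families overlap the list of RNAs without a poly(A) tail, so their values are in part the same result. The median was 1.30 for H2B, 1.04 for H3 and 1.38 for H4, and 0.91, 0.64 and 0.99 under total counts. H2A, which holds most of the histone TPM, had a median of 0.75 (0.35 under total counts), with 7 genes at least 2-fold higher in replicate 2 and 4 at least 2-fold lower, and its sum was 38477 TPM in replicate 1 and 40168 TPM in replicate 2. Linker histones had -0.30 over 4 genes (52.2nd percentile). All histone genes together took 1.23% of counts in replicate 1 (95% Wilson interval 1.22 to 1.23%) and 1.14% in replicate 2 (1.13 to 1.15%). Histone genes are near-identical copies, so values of single members are uncertain.

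The 13 mitochondrially encoded messenger genes had a median of -1.94, with 9 at least 2-fold lower in replicate 2 and 3 at least 2-fold higher. Summed, these genes had 3192 TPM in replicate 1 and 2502 TPM in replicate 2. Within them mt-Atp6 had 226 and 0 TPM while mt-Atp8, whose reading frame overlaps it, had 666 and 1456 TPM. Summing similar genes changed the size of some differences in TMM-scaled counts. Rps3a genes together had 8550 and 53 counts, 24.0-fold apart, and Rpl27 with its pseudogenes was 8.23-fold apart. Rpsa with its pseudogenes was 2.40-fold higher in replicate 1, opposite in direction to Rpsa-ps2 alone. Hba-a1 and Hba-a2 together were 1.67-fold higher in replicate 1 on this scale, and had 104220 TPM in replicate 1 and 37609 TPM in replicate 2.

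The ribosomal RNA region of Gm42418 and Gm26917 took 1.42% of TPM in replicate 1 and 4.05% in replicate 2. The median log2 ratio between the libraries also moved with expression, from -0.48 at a mean CPM of 1 to 3 to 0.90 at a mean CPM of at least 1000. All 1569 annotated genes of the Y chromosome together held 5 and 4 counts. The X-linked homologs were present, with 22181 and 1939 counts for Kdm5c and 3547 and 41 counts for Ddx3x.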
